A study of Mus musculus with 26 samples.

How the data were processed

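RNA from 26 samples of transplanted HCmel3 mouse melanomas was measured on Illumina MouseWG-6 v2.0 bead arrays, 1 array per sample. HCmel3 is a melanoma that grows in C57BL6 mice. Tumours were excised and frozen in liquid nitrogen, and 100 ng of total RNA was amplified and labelled with biotin, per the labels' protocols. The arrays were deposited in 2 tables. The first holds 8 untreated tumours (NT) and 8 tumours taken early during treatment (EDT), between day 12 and day 20 after the onset of adoptive T cell transfer. The second holds 5 untreated control tumours (ctrl) and 5 tumours that had relapsed after the transfer (relapse). The treatment combined cyclophosphamide, intravenous CD8+ pmel-1 T cells that recognise the melanocyte antigen gp100, an adenovirus vaccine expressing gp100, and innate stimulation with CpG and polyI:C, per the labels. Sample titles of the second table note a repeated analysis, and whether RNA was measured again or data were processed again is not stated. Groups and replicate numbers were taken from the labels. Samples are called tumours below, but no label states that those of a group came from separate animals, so p-values measure the spread between these samples, which may be partly technical.

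The deposited tables give the mean bead signal per probe as an intensity that was neither background-corrected nor normalized, as the values themselves show. Detection p-values are deposited beside each signal and are the share of negative control beads at least as bright as the probe. In the second table the authors also deposited, per the file headers, a standard error of the bead signals and a number of beads per probe, and these were not used in any comparison. The authors' processed values are on a log2 scale, as found by setting each array's values against its own scanner signals: they kept the rank order of the signals in each array and rose with a slope near 1 above a signal of 2000. Array medians of these values lay between 4.66 and 4.86, no centring of genes was seen, and the method behind them, the scanner software and any step before export are not given in the sources used here. They were used as an alternative only.

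The first table held 45264 probes and the second 45281. In 4 probe rows of the first table signals and detection p-values were exchanged or mistyped, and these probes were left out, together with 17 probes found only in the second table, which left 45260. Gene symbols came from the platform annotation supplied for the arrays: 34871 probes had 1 symbol, 18 had several and 10371 had none, and updating through gene identifiers changed 0 symbols. Only probes with 1 symbol were named. Genes to which that annotation gives no probe with 1 symbol, such as Lck, Gzma, Ly6g and Cd68, could not enter the lists. Each table was background-corrected with negative controls inferred from the detection p-values, given an offset of 16 and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3. A probe was kept with a detection p under 0.01 on at least 5 arrays of at least 1 group, which 16624 probes passed, 14472 of them with 1 symbol. Each of the 9553 genes was represented by its brightest passing probe over the 26 arrays, and 3463 genes had more than 1 passing probe.

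Genes were compared with lmFit and eBayes of limma, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. EDT was compared with NT and relapse with ctrl, each within its own table. The difference of effects, the EDT effect minus the relapse effect, was fitted over all 26 arrays with 4 group means. Because the tables were normalized apart, levels were not compared between them. Where no array of a control group detected a gene's probe, the control level was set, array by array, to the lowest normalized signal that the array detected or to the probe's own signal where that was higher, and the fold is given as a lower bound.

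Before the data were examined, 23 gene lists were fixed for tumour cell states, immune cell types and programmes, and other tissues that a tumour piece can hold. The score of a list in a tumour was the mean log2 signal of its tested members. Differences of mean scores were tested by two-sided exact permutation over all splits, with adjustment over the 23 lists. The smallest p the design allows is 0.000155 for 8 against 8 and 0.00794 for 5 against 5. Camera with a preset correlation of 0.01, camera with an estimated correlation and fry were run beside them. Camera with an estimated correlation called 0 lists in either comparison, so each call of a fixed list below stands with its p under that test. Camera asks whether the genes of a list change more than the other genes. The permutation asks whether the list score differs between groups, and correlation between members already enters the spread of the scores. The camera p therefore answers another question and does not repeat the permutation test. Relations between list scores across tumours, 6 in all, were tested with exact permutation of the pairings. Errors of log2 changes are standard errors (SE), and errors of levels are standard deviations (SD).

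Genes are named by a rule fixed before the data were examined: the 5 highest and the 5 lowest changes past the threshold, the 2 largest changes past the threshold in each tumour or immune list, the largest in each list of another tissue, the brightest member of a list with none past the threshold, and always Pmel, Hgf and Met. Other members of the lists are given as examples where a small count calls for them, and were then chosen after their values were seen.

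Arrays lay on 7 slides. Slide 1 held NT replicates 1 to 3, slide 2 EDT replicates 1 to 3, slide 3 EDT replicates 4 to 6 and slide 4 NT replicates 4 and 5. Slide 5 held 3 NT and 2 EDT tumours and was the only mixed slide of the first table. Slides 6 and 7 of the second table held 3 and 2 tumours of each group. Slide was tried as a random and as a fixed block and within each mixed slide. With slide as a fixed block, only slide 5 informs the difference between EDT and NT, so the block and slide 5 give the same value and differ in the error.

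Other alternatives were quantile normalization without background correction, median centring in place of quantile normalization, both tables normalized together, the authors' processed values, a detection p of 0.05, no detection filter, the mean over all probes of a gene, a 2-fold minimum, array weights, eBayes with trend and robust settings, replicate number as a block, Spearman in place of Pearson correlation, and leaving out each tumour in turn. Leaving out slide 1, whose raw signals were the lowest of the first table, was added after seeing the data. So were relations with scores centred within slide, and slides 5 and 7 without 1 control tumour each.

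The scripts were tested on simulated data with 9553 genes and known changes. With the sizes and spread of EDT against NT, 82% of changes of 1 and 98% of changes of 2 on the log2 scale were recovered. For relapse against ctrl these shares were 37% and 87%, and for the difference of effects 34% and 84%. In the simulation genes varied independently, 100 genes were changed by each size, and the difference of effects used the spread of relapse and ctrl for all arrays. In the real data genes were correlated and far more were called, so these shares test the scripts and are not the power reached here. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.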

Results

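Gene expression was measured in 26 samples of HCmel3 melanomas: 8 untreated tumours (NT), 8 tumours early during adoptive pmel-1 T cell transfer (EDT, day 12 to day 20), 5 untreated controls (ctrl) and 5 relapsed tumours (relapse). NT arrays detected 14955 ± 691 probes (SD, n = 8; range 14064 to 16312) and EDT arrays 15982 ± 564 (SD, n = 8; 15008 to 16830), a difference of 1026.5 probes (two-sided exact permutation p = 0.00793). Control arrays of the second table detected 16013 ± 1047 probes (SD, n = 5; 14545 to 17033) and relapse arrays 17609 ± 951 (SD, n = 5; 15992 to 18323), a difference of 1595.2 (exact permutation p = 0.0397). The 95th percentile of the raw signal was higher by 0.44 on the log2 scale in EDT than in NT (exact permutation p = 0.0522) and by 0.38 in relapse than in ctrl (exact permutation p = 0.0476). Pairs of replicates correlated across the tested genes with r between 0.932 and 0.983 in NT, 0.893 and 0.981 in EDT, 0.939 and 0.967 in ctrl, and 0.853 and 0.970 in relapse.

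The first comparison asked how gene expression in tumours taken early during T cell transfer differed from that in untreated tumours. The treatment also held cyclophosphamide, an adenovirus vaccine, CpG and polyI:C. No group received a part of it alone, so the effects of the parts cannot be told apart in either comparison. Genes of T cells, antigen presentation and the interferon response rose in EDT tumours, while part of the melanocyte differentiation genes fell. Ubd, an interferon-inducible ubiquitin-like modifier, rose by 6.81 ± 0.34 on the log2 scale (SE, n = 8 and 8) from a signal that 1 of 8 NT arrays detected, and the chemokine Cxcl9 by 5.91 ± 0.37, which is 60.1-fold. Transcripts of the CD3 chains, which form the signalling part of the T cell receptor, were not detected on any NT array and were at least 22.7-fold (Cd3d) and at least 19.1-fold (Cd3g) higher in EDT. The MHC class II genes H2-Eb1 and H2-Ab1 rose by 3.76 ± 0.42 and 3.58 ± 0.37, and the melanosomal transporter gene Oca2 fell by 2.23 ± 0.44.

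Of 9553 genes, 2831 differed at an adjusted p of 0.05 in limma, 1385 higher and 1446 lower in EDT, and 3894 had an unadjusted p under 0.05. The split between directions hung on the scaling: 2275 were higher and 174 lower with median centring, and 1747 and 756 with the authors' values. At 2-fold or more, 650 were higher and 204 lower. Besides Ubd and Cxcl9, the highest changes were those of Trbv13-2, a T cell receptor beta variable segment (6.63 ± 0.43), the serine protease inhibitor gene Serpina3f (6.33 ± 0.41) and Acod1, the enzyme that makes itaconate in activated macrophages (5.12 ± 0.39). Each had a limma adjusted p of at most 5.3e-08 and lay above every NT tumour in 8 of 8. The lowest changes were those of the pseudogene Cyp4b1-ps2 (-3.64 ± 0.53), the monooxygenase gene Cyp4b1 (-3.62 ± 0.57), Cdhr1 (-2.90 ± 0.55), Trnp1 (-2.84 ± 0.36) and the T-box factor Tbx4 (-2.76 ± 0.59). Cyp4b1 and its pseudogene are close in sequence, and their probes cannot be taken as separate measurements. Changes from or to signals near background are not exact. Besides Ubd, NT arrays detected Fpr2, Lag3 and Nt5e on 1 of 8, Acod1, Ctsw, Clec4e and Cd22 on 2, Serpina3f and Nkg7 on 3 and Trbv13-2 and Il1b on 4. EDT arrays detected Cdhr1 on 1 of 8, Tbx4 on 2, Cyp4b1 on 5 and its pseudogene on 6. With slide as a fixed block 1045 genes differed (612 higher, 433 lower), and within slide 5 alone, with 2 against 3 tumours, 480 did (410 higher, 70 lower). With slide as a random block the count was 2458. Of 43 called genes that were followed one by one, 12 lost the call with slide as a fixed block. The change was smaller for Oca2 (-1.33, limma adjusted p = 0.215), Trpm1 (-0.55, limma adjusted p = 0.742), Il1b (1.87), Top2a (0.54), Tyms (0.48), Egln3 (0.75) and Vwf (-1.49). For Trpm1 this rests in part on NT replicate 6, which lies on slide 5 and was low for it: without that tumour slide 5 gave -1.46 (limma adjusted p = 0.177). It was larger for Cdhr1 (-3.44), Axl (2.03), Met (-1.20), Lpl (1.32) and Atf3 (1.66). On slide 5 alone 16 lost it, these 12 with the same changes and Cyp4b1 (-4.37), Tbx4 (-3.88), Nt5e (2.10) and Fn1 (1.93), of which only Nt5e had the smaller change there.

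T cell genes rose together in EDT. Of 12 tested members of the T cell list (18 fixed), 12 rose, and 12 did adjusted over the list alone. The smallest change was that of the CD8 chain gene Cd8b1 (0.37). Probes of Cd8a were below the detection filter in every group. The list score was higher by 2.47 ± 0.36 (SE, n = 8 and 8, adjusted exact p = 0.000447) and by 2.60 on slide 5. It had an adjusted p = 0.152 with an estimated correlation. Quantile normalization without background correction gave 1.46. Among cytotoxic and natural killer genes 10 of 11 rose (17 fixed), over the list alone also 10. Nkg7 and Ctsw, both carried by cytotoxic lymphocytes, rose by 4.53 ± 0.54 and 4.26 ± 0.41, whereas the perforin gene Prf1 had a change of 0.09. The cytotoxic score was higher by 2.28 ± 0.35 (adjusted exact p = 0.000447), by 2.39 on slide 5 and by 1.39 without background correction. Its adjusted p = 0.152 with an estimated correlation.

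Antigen presentation and interferon genes rose almost throughout. Of 16 MHC class I presentation genes 15 rose, with Psmb9, a subunit of the immunoproteasome, at 3.58 ± 0.29 and the peptide transporter Tap1 at 3.32 ± 0.26, while B2m had a change of 0.28. The score was higher by 2.06 ± 0.17 (adjusted exact p = 0.000447), by 2.36 on slide 5, and had an adjusted p = 0.0525 with an estimated correlation. MHC class II presentation rose in 10 of 10 tested genes (11 fixed), with a score difference of 2.60 ± 0.25 (adjusted exact p = 0.000447), 3.32 on slide 5, and an adjusted p = 0.0525 with an estimated correlation. Of 20 tested interferon response genes (29 fixed) 19 rose, 20 adjusted over the list alone. Besides Cxcl9, the interferon-inducible GTPase Igtp rose by 4.79 ± 0.32. The interferon score was higher by 2.39 ± 0.20 (adjusted exact p = 0.000447), by 2.57 on slide 5, with an adjusted p = 0.0525 under an estimated correlation.

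Myeloid groups rose as well. Of 18 macrophage and monocyte genes (21 fixed) 16 rose, among them the calcium-binding protein gene Aif1 (3.02 ± 0.32) and the lysozyme gene Lyz2 (2.52 ± 0.27). The score was higher by 1.66 ± 0.21 (adjusted exact p = 0.000447), by 1.71 on slide 5, with an adjusted p = 0.0774 under an estimated correlation. Neutrophil genes rose in 8 of 13 tested (27 fixed), including the formyl peptide receptor Fpr2 (4.82 ± 0.52) and the lectin Clec4e (3.18 ± 0.48). Their score was higher by 2.07 ± 0.61 (adjusted exact p = 0.011) and by 1.77 on slide 5, where the limma adjusted p was 0.0267. As a fixed block, slide ended this call (limma adjusted p = 0.145). The neutrophil list had an adjusted p = 0.247 with an estimated correlation. The score of the keratinocyte list, whose tissue shares S100a8, S100a9, Lcn2 and Stfa1 with neutrophils, differed by 1.36 ± 1.71 (adjusted exact p = 0.517).

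Among genes of neutrophil attraction and acute inflammation 9 of 11 rose (20 fixed), with the chemokine Ccl4 at 3.12 ± 0.39 and the cytokine Il1b at 2.64 ± 0.72, the latter above the NT mean in 7 of 8 tumours. The score was higher by 1.84 ± 0.41 (adjusted exact p = 0.00119), by 1.64 on slide 5, and the call ended with slide as a fixed block (limma adjusted p = 0.081). This list had an adjusted p = 0.191 with an estimated correlation. Dendritic cell genes rose in 3 of 6 (12 fixed), Ccr7, Cd83 (2.01 ± 0.33) and Clec9a, the last at least 1.05-fold. The dendritic cell score was higher by 0.71 ± 0.15 (adjusted exact p = 0.000447), by 1.17 on slide 5, with an adjusted p = 0.243 under an estimated correlation. Only 2 of 13 B cell and plasma cell genes were tested, and Cd22 rose by 0.73 ± 0.26, a call that ended when NT replicate 1, 6, 7 or 8 or EDT replicate 2, 4, 5, 6, 7 or 8 was left out, with changes between 0.61 and 0.75, and without background correction (0.29, limma adjusted p = 0.0583). The B cell score was higher by 0.54 ± 0.18 (adjusted exact p = 0.0197), by 0.80 on slide 5 (limma adjusted p = 0.15, and 0.103 as a fixed block), and its adjusted p = 0.394 with an estimated and 0.284 with a preset correlation. Without a detection filter it was 0.12 (adjusted exact p = 0.0679). Immune checkpoint and regulatory genes rose in 8 of 10 (15 fixed; over the list alone 8 rose and 1 fell), led by the PD-1 ligand Cd274 (3.37 ± 0.33) and the inhibitory receptor Lag3 (3.13 ± 0.32). The checkpoint score was higher by 1.33 ± 0.18 (adjusted exact p = 0.000447), by 1.51 on slide 5, with an adjusted p = 0.145 under an estimated correlation.

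Melanocyte differentiation genes were lower in part. Of 17 tested (18 fixed) 8 fell, 14 adjusted over the list alone, among them Oca2 and the channel gene Trpm1 (-2.07 ± 0.58). Pmel, which encodes gp100, the antigen of the transferred T cells, had a change of -0.51 ± 0.26 (limma adjusted p = 0.141) and was below the NT mean in 5 of 8 tumours, and its other probe gave -1.09. With the mean over probes Pmel was lower by 0.80 and passed (limma adjusted p = 0.0318), so whether it fell hung on the probe. The list score fell by 0.99 ± 0.25 (SE, n = 8 and 8, adjusted exact p = 0.0032) and lay below every NT tumour in 5 of 8. It was -0.65 with median centring (adjusted exact p = 0.0491) and -0.53 on slide 5 (limma adjusted p = 0.388, and 0.312 as a fixed block; -0.72 without NT replicate 6), and had an adjusted p = 0.303 with an estimated correlation. In the neural crest and dedifferentiation list 4 of 11 genes rose (16 fixed) and 1 fell: the ectonucleotidase Nt5e (2.17 ± 0.34), the receptor kinase Axl (1.86 ± 0.31), Tnc and Snai2 rose, and Sox9 fell. The score was higher by 0.63 ± 0.18 (adjusted exact p = 0.0078), by 0.38 on slide 5 (limma adjusted p = 0.534, and 0.485 as a fixed block), with an adjusted p = 0.3 under an estimated correlation. Whether tumour cells or other cells of the tumour pieces carried the genes of this list was not tested in either comparison.

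Endothelial genes fell in 3 of 12 (13 fixed), the clotting factor gene Vwf (-1.69 ± 0.30), Esam and Sox18. The endothelial score fell by 0.54 ± 0.16 (adjusted exact p = 0.0104), with an adjusted p = 0.394 under an estimated correlation. It lay at -0.70 on slide 5, where the limma adjusted p was 0.163 (0.0788 as a fixed block), and median centring gave -0.18 (adjusted exact p = 0.351). For the receptor tyrosine kinase gene Met the change was -1.10 ± 0.26 (limma adjusted p = 0.00388). It was -1.20 on slide 5 (limma adjusted p = 0.119) and -0.71 with median centring (limma adjusted p = 0.0728). None of the 3 probes of its ligand gene Hgf passed the detection filter, and only 2 relapse arrays detected one. The HGF and MET list had a difference of -0.07 ± 0.14 (adjusted exact p = 0.67; 1 of 4 fell, and adjusted over the list alone 1 rose and 1 fell).

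Other lists did not pass. Cell cycle had a difference of 0.13 ± 0.10 (adjusted exact p = 0.313) and passed with median centring (0.48, adjusted exact p = 0.0274). Of its 22 genes 4 rose, among them Top2a (0.74 ± 0.15) and Tyms (0.58 ± 0.20). The Tyms call ended without NT replicate 1 or 5 or EDT replicate 1, 2, 3 or 8, with changes between 0.46 and 0.58. Hypoxia and glycolysis differed by 0.06 ± 0.17 (adjusted exact p = 0.786), with a median over members of -0.07, with Egln3 higher (1.37 ± 0.34) and Ndrg1 lower (-1.22 ± 0.17). Fibroblast and matrix genes had a difference of 0.72 ± 0.31 (adjusted exact p = 0.0648), with 4 of 15 genes higher, fibronectin (Fn1) by 1.80 ± 0.30, and the list passed without EDT replicate 1 (0.87, adjusted exact p = 0.02) or 6 (0.88, adjusted exact p = 0.0146). It also passed with the authors' values (0.82, adjusted exact p = 0.038), median centring (1.05, adjusted exact p = 0.0074) and a preset correlation (adjusted p = 0.00885). Immediate early and stress genes differed by 0.41 ± 0.26 (adjusted exact p = 0.195), with Atf3 higher (1.37 ± 0.37), and passed with median centring (0.77, adjusted exact p = 0.00605). Adipocyte genes differed by 0.48 ± 0.51 (adjusted exact p = 0.479), with Lpl higher (1.24 ± 0.32). Skeletal muscle genes differed by -0.02 ± 0.95 (adjusted exact p = 0.981; median over members 0.18) and erythroid genes by -0.48 ± 0.73 (adjusted exact p = 0.593). Krt14, Myl1 and Hba-a1, the brightest members of the keratinocyte, muscle and erythroid lists, had changes of 1.16 ± 1.81, 0.98 ± 1.26 and -0.10 ± 0.37. On slide 5 the differences of hypoxia (-0.26), keratinocyte (-0.42), muscle (1.21) and erythroid genes (0.24) and the changes of Krt14 (-0.46) and Hba-a1 (0.0904) had the opposite sign.

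Within the 8 EDT tumours, the T cell score and the melanocyte score were related inversely (Pearson r = -0.94, adjusted exact permutation p = 0.0112; Spearman rho = -0.79, adjusted p = 0.0419), as were the neutrophil and melanocyte scores (r = -0.88, adjusted exact p = 0.0134; rho = -0.88, adjusted p = 0.0321). The T cell and neutrophil scores were related directly (r = 0.79, adjusted exact p = 0.0383; rho = 0.81, adjusted p = 0.0419). Raw exact p-values of these r were 0.00186, 0.00446 and 0.0191, in a family of 6 relations. Without the 2 tumours farthest from the median of the first score, r was -0.82 (exact p = 0.0722), -0.78 (exact p = 0.0708) and 0.58 (exact p = 0.231), so that none of the 3 passed without them. With single tumours left out, T cells with melanocytes no longer passed without EDT replicate 2 (r = -0.88, adjusted exact p = 0.0649), and neutrophils with melanocytes without replicate 2 (r = -0.88, adjusted exact p = 0.0649) or 6 (r = -0.84, adjusted exact p = 0.0583). T cells with neutrophils no longer passed without EDT replicate 1, 2, 3, 5, 6 or 7, with r between 0.70 and 0.81. Median centring gave r = -0.67 for neutrophils with melanocytes (adjusted exact p = 0.132). The labels give day 12 to day 20 for the EDT group and no day per tumour, so an influence of the day on these relations could not be tested. Scores of leukocyte and tumour genes from the same mixed sample also depend on the shares of the cells, so these relations do not show which process links them.

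In the 8 NT tumours the melanocyte score and the T cell score, which spread little there (SD 0.17, n = 8), were related by Spearman's rho and not by Pearson's r (r = 0.66, adjusted exact p = 0.108; rho = 0.86, adjusted p = 0.0321). Pearson's r was 0.86 without the 2 farthest tumours (exact p = 0.0306), and r passed as well without NT replicate 6 (0.81, adjusted exact p = 0.0411) or 8 (0.79, adjusted exact p = 0.0363). Since 0 of 8 NT arrays detected Cd3d or Cd3g, these ranks rest in part on signals near background. For T cells with neutrophils (r = 0.25, adjusted exact p = 0.545; rho = 0.43, adjusted p = 0.299; 0.27 without the 2 farthest) and neutrophils with melanocytes (r = 0.29, adjusted exact p = 0.545; rho = 0.57, adjusted p = 0.181; 0.47 without the 2 farthest) neither statistic passed in NT. With scores centred within slide and permuted within slides, r in EDT was -0.94 for T cells with melanocytes, -0.87 for neutrophils with melanocytes and 0.81 for T cells with neutrophils, each with an adjusted exact p = 0.0833. The 72 orders of tumours within slides allow no p under 0.0139. In NT r was 0.42, -0.52 and -0.41, and none passed.

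**Figure D1:**
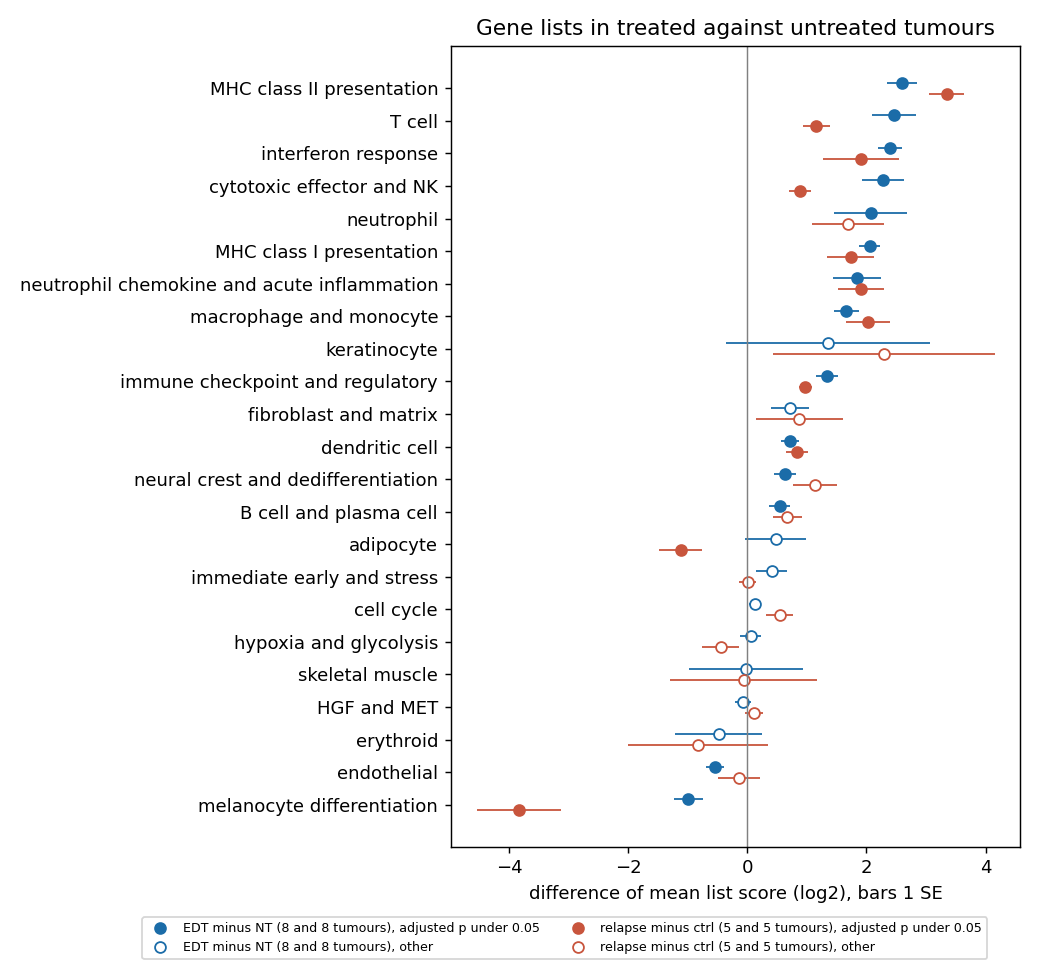
Difference of the mean list score on the log2 scale (horizontal axis) for the 23 gene lists (vertical axis), EDT minus NT in blue and relapse minus ctrl in red, with bars of 1 SE and filled points for an adjusted exact p under 0.05. MHC class II presentation lies at 2.60 and 3.35, and melanocyte differentiation at -0.99 and -3.83.

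The second comparison asked how tumours that relapsed after T cell transfer differed from untreated tumours. Melanocyte differentiation genes were much lower in relapsed tumours, and MHC class II genes were much higher. Oca2 fell by 6.19 ± 0.88 on the log2 scale (SE, n = 5 and 5), which is 73.1-fold, and Trpm1 by 5.98 ± 0.83. Cd74, the MHC class II invariant chain, rose by 5.58 ± 0.45, or 47.7-fold, H2-Eb1 by 5.33 ± 0.41 and H2-Ab1 by 5.18 ± 0.43. Pmel fell by 4.68 ± 1.13 (limma adjusted p = 0.00985), below every control tumour in 5 of 5, with a level of 10.5 ± 3.04 in relapse against 15.1 ± 0.101 in ctrl (SD, n = 5 each, log2).

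Of 9553 genes, 2944 differed in limma, 1270 higher and 1674 lower in relapse, and 4160 had an unadjusted p under 0.05. Median centring gave 2085 higher and 656 lower, and the authors' values 1535 and 1314. At 2-fold or more, 878 were higher and 954 lower. Among the highest were also Ly6e, an interferon-inducible surface protein (4.98 ± 0.51), and the kinase gene Prkg2 (4.89 ± 0.70). Among the lowest were the noncoding RNA Lncbate10 (-5.74 ± 0.57), the tetraspanin Tspan10 (-5.51 ± 0.98) and the synaptotagmin Syt4 (-5.30 ± 0.87). Each had a limma adjusted p of at most 0.00235 and lay beyond every control tumour in 5 of 5. Relapse arrays detected Trpm1 and Lncbate10 on 2 of 5, Tspan10 on 3 and Oca2 on 4, so these falls reach background in some tumours and are not exact. Control arrays detected Cd79b and Gm9780 on 1 of 5, Fpr2 and Il1b on 2, and Nkg7, Cxcl10, Cd83, Havcr2 and Vsir on 3. Slide as a fixed block gave 3058 genes, slide 6 alone 568 and slide 7 alone 2441, with 3 and 2 tumours per group. Of 41 called genes that were followed one by one, 16 lost the call on slide 6 alone. Among them were Oca2 (-5.48, limma adjusted p = 0.0501), Trpm1 (-5.07, limma adjusted p = 0.0512) and Pmel (-4.18, limma adjusted p = 0.193), with changes nearly as large. On slide 7 alone 9 lost it, among them Cxcl10 (2.95, limma adjusted p = 0.0601) and Cxcl9 (0.52, limma adjusted p = 0.803), and with slide as a fixed block 0 did. Without ctrl replicate 5, 1 of 2 control tumours on slide 7 and high for Cxcl9, the Cxcl9 change there was 2.84 (limma adjusted p = 0.0155). Without relapse replicate 3, whose melanocyte genes were the least reduced, 3938 genes differed.

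Every tested member of the melanocyte differentiation list fell, 17 of 17 (18 fixed), also over the list alone. The score fell by 3.83 ± 0.71 (SE, n = 5 and 5, adjusted exact p = 0.0203), which is 14.3-fold lower, with -3.27 on slide 6 and -4.67 on slide 7, and had an adjusted p = 0.252 with an estimated correlation. In the neural crest and dedifferentiation list 3 of 11 genes rose, Nt5e (3.57 ± 0.71), Axl (3.14 ± 0.46) and Tnc, and Sox9 fell. Its score difference of 1.14 ± 0.37 had an adjusted exact p = 0.0702, with 0.96 on slide 6, 1.41 on slide 7 and a limma adjusted p = 0.027 with slide as a fixed block. It also passed with median centring (1.46, adjusted exact p = 0.0421), with the mean over probes (adjusted exact p = 0.0498) and without relapse replicate 3 (1.46, adjusted exact p = 0.0183).

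MHC class II presentation rose in 10 of 10 genes, with a score difference of 3.35 ± 0.30 (adjusted exact p = 0.0203), 3.44 on slide 6 and 3.21 on slide 7, and an adjusted p = 0.15 with an estimated correlation. MHC class I genes rose in 12 of 16, 14 over the list alone, with the immunoproteasome subunit Psmb8 at 4.2 ± 0.68 and the nonclassical class I gene H2-M3 at 2.78 ± 0.37. Their score was higher by 1.74 ± 0.40 (adjusted exact p = 0.0203), by 2.38 on slide 6 but by 0.77 on slide 7 (limma adjusted p = 0.346), with an adjusted p = 0.252 under an estimated correlation. Of 20 interferon response genes 11 rose, 12 over the list alone, with the chemokines Cxcl10 at 4.01 ± 0.64 and Cxcl9 at 3.96 ± 1.08. The interferon score was higher by 1.91 ± 0.64 (adjusted exact p = 0.0498), by 2.83 on slide 6 and by 0.52 on slide 7 (limma adjusted p = 0.563; 1.40 without ctrl replicate 5, limma adjusted p = 0.143), and had an adjusted p = 0.405 with an estimated correlation. This call ended when ctrl replicate 1, 2, 3 or 4 or relapse replicate 1, 2, 3 or 4 was left out, with differences between 1.59 and 2.08, and with no detection filter (adjusted exact p = 0.0664) or a detection p of 0.05 (adjusted exact p = 0.0608).

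T cell genes rose in 7 of 12, also over the list alone, with Cd3g at least 3.80-fold and Cd3d at least 3.70-fold higher than in control tumours, none of which detected them. The T cell score was higher by 1.16 ± 0.23 (adjusted exact p = 0.0203), by 1.47 on slide 6 and 0.71 on slide 7 (limma adjusted p = 0.346), and had an adjusted p = 0.252 with an estimated correlation. Without background correction it was 0.52. Cytotoxic and natural killer genes rose in 4 of 11 and 1 fell (5 and 1 over the list alone): the chemokine Ccl5 rose by 3.94 ± 0.48, Nkg7 by 2.07 ± 0.50, and Klrd1 and Ctsw rose too, while Prf1 fell by 1.26. Their score was higher by 0.88 ± 0.18 (adjusted exact p = 0.0203), by 1.22 on slide 6 and 0.38 on slide 7 (limma adjusted p = 0.533), with an adjusted p = 0.252 under an estimated correlation and a difference of 0.47 without background correction.

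Macrophage and monocyte genes rose in 13 of 18, 14 over the list alone, with Aif1 at 3.60 ± 0.41 and the complement gene C1qc at 3.30 ± 0.44. The score was higher by 2.02 ± 0.37 (adjusted exact p = 0.0203), by 1.62 on slide 6 and 2.63 on slide 7, with an adjusted p = 0.252 under an estimated correlation. Acute inflammation genes rose in 7 of 11, Il1b by 4.03 ± 0.54 and Ccl7 by 3.32 ± 0.36, with a score difference of 1.91 ± 0.39 (adjusted exact p = 0.0203), 1.83 on slide 6, 2.02 on slide 7, and an adjusted p = 0.252 with an estimated correlation. Neutrophil genes rose in 6 of 13, 7 over the list alone, Fpr2 by 3.40 ± 0.46 and Lcn2 at least 2.35-fold, while the neutrophil score difference of 1.70 ± 0.60 had an adjusted exact p = 0.0702, with 1.06 on slide 6 and 2.65 on slide 7 (limma adjusted p = 0.0123). The keratinocyte list, whose tissue shares Lcn2 and other members with neutrophils, was higher by 4.38 on slide 7 (limma adjusted p = 0.0612) and by 0.91 on slide 6. The neutrophil list passed with a preset correlation (adjusted p = 0.000434), with slide as a fixed block (limma adjusted p = 0.0279) and without relapse replicate 1 (2.23, adjusted exact p = 0.0183), and the Lcn2 call ended without ctrl replicate 3 or 4 or relapse replicate 4 or 5 and without background correction (limma adjusted p = 0.0523).

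Checkpoint genes rose in 5 of 10, 7 over the list alone, Havcr2 by 1.97 ± 0.32 and Vsir by 1.78 ± 0.49. Their score was higher by 0.97 ± 0.11 (adjusted exact p = 0.0203), by 0.96 on slide 6 and 1.0 on slide 7 (limma adjusted p = 0.168), with an adjusted p = 0.124 under an estimated correlation. Of 6 dendritic cell genes 1 rose, Cd83 (2.56 ± 0.40), with a score difference of 0.84 ± 0.18 (adjusted exact p = 0.0203), 0.82 on slide 6, 0.86 on slide 7 (limma adjusted p = 0.329), and an adjusted p = 0.252 with an estimated and 0.095 with a preset correlation. Cd79b rose by 1.40 ± 0.31, and the B cell score difference was 0.67 ± 0.24 (adjusted exact p = 0.0782), which passed with median centring (0.96) or a detection p of 0.05 (0.68). The score of adipocyte genes fell by 1.12 ± 0.36 (adjusted exact p = 0.0365), with an adjusted p = 0.58 under an estimated and 0.326 under a preset correlation. Only 1 of 4 fell, Pparg (-3.53 ± 0.48), a nuclear receptor that is also active outside fat tissue. The adipocyte score was -1.27 on slide 6 and -0.89 on slide 7 (limma adjusted p = 0.341), and its call ended without ctrl replicate 1, 2 or 4 or relapse replicate 1, 2, 3 or 4, with differences between -1.23 and -0.89. It also ended with median centring (-0.85, adjusted exact p = 0.158) and with the mean over probes (-0.86, adjusted exact p = 0.0608).

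Other lists did not pass in relapse. Endothelial genes differed by -0.14 ± 0.36 (adjusted exact p = 0.782), with Vwf lower (-2.24 ± 0.35). Fibroblast and matrix genes differed by 0.88 ± 0.74 (adjusted exact p = 0.325), with Fn1 higher (2.73 ± 0.75), and cell cycle genes by 0.54 ± 0.23 (adjusted exact p = 0.0974), with 6 of 22 higher, Top2a by 1.67 ± 0.33 and Tyms by 1.37 ± 0.42. The cell cycle list passed with slide as a fixed block (limma adjusted p = 0.0441) and without ctrl replicate 5 (0.72, adjusted exact p = 0.0365). It also passed with median centring (0.93, adjusted exact p = 0.0203), the authors' values (0.65, adjusted exact p = 0.0456) and a preset correlation (adjusted p = 0.00167). The Tyms call ended without ctrl replicate 2 or 4 or relapse replicate 4 or 5, with changes between 1.23 and 1.38. Hypoxia and glycolysis differed by -0.44 ± 0.31 (adjusted exact p = 0.285), with Egln3 higher (1.98 ± 0.34) and Ndrg1 lower (-1.57 ± 0.42), and passed without relapse replicate 3 (-0.70, adjusted exact p = 0.0498). The HGF and MET list differed by 0.11 ± 0.15 (adjusted exact p = 0.593), while its median over members was -0.62 and fry called it lower (adjusted p = 0.0257). Spint1, an inhibitor of the protease that activates HGF, rose by 2.67 ± 0.58. Gab1 (-0.96 ± 0.20, and -0.69 with median centring, limma adjusted p = 0.0525) and Plxnb1 fell, and Met had a change of -0.60 ± 0.29 (limma adjusted p = 0.132). Keratinocyte genes differed by 2.30 ± 1.86 (adjusted exact p = 0.322), and muscle genes by -0.06 ± 1.24 (adjusted exact p = 0.968). Erythroid genes differed by -0.82 ± 1.18 (adjusted exact p = 0.567) and immediate early genes by 0.01 ± 0.15 (adjusted exact p = 0.968), with Fos lower (-1.79 ± 0.46). Krt14, Myl1 and Hba-a1 had changes of 2.93 ± 1.95, 0.29 ± 1.14 and -1.45 ± 1.02. On slide 6 muscle (0.91) and immediate early genes (-0.13) and on slide 7 endothelial genes (0.46) and Myl1 (-0.80) had the opposite sign. Krt14 passed within slide 7 (6.15, limma adjusted p = 0.0489) and without relapse replicate 1 (4.71), and Hba-a1 passed without relapse replicate 3 (-2.30).

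**Figure D2:**
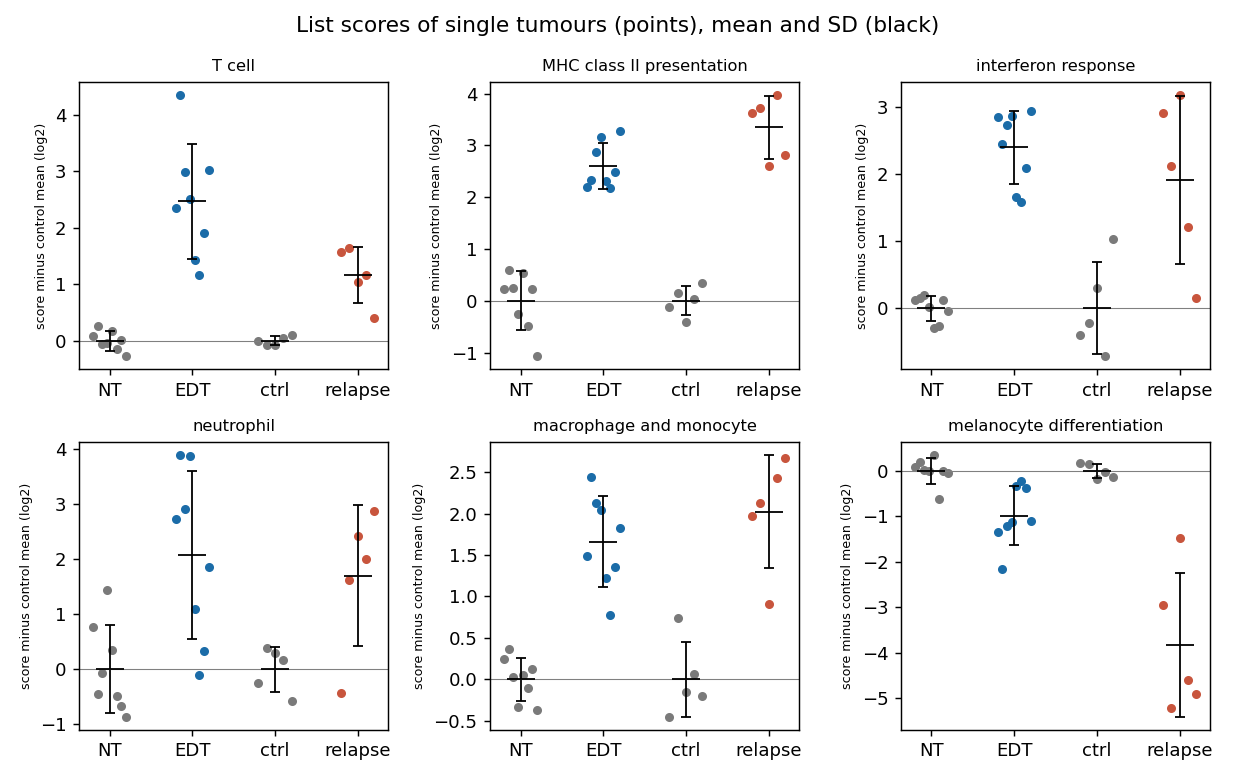
List scores of the 26 tumours (points) minus the mean of their own control group, on the log2 scale (vertical axis), for 6 gene lists in the groups NT, EDT, ctrl and relapse (horizontal axis), with mean and SD in black. Melanocyte differentiation lay below every untreated tumour in 5 of 8 EDT and 5 of 5 relapse tumours, with mean differences of -0.99 and -3.83.

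The last comparison asked whether genes changed by different amounts early during treatment and at relapse. Melanocyte genes fell further at relapse than early during treatment: the EDT effect minus the relapse effect was 4.42 ± 0.81 for Mlana (SE, limma), 4.16 ± 1.02 for Pmel and 4.14 ± 0.78 for Rab38, a regulator of melanosome transport. The melanocyte list score differed by 2.85 ± 0.62 (limma adjusted p = 0.00247). It was the only 1 of 23 lists to pass in the fit with all tumours, with cytotoxic genes at an adjusted p = 0.068 and T cell genes at 0.105. This fit pools 1 spread over the 4 groups and was not run as a permutation. The SD of the melanocyte score was 1.58 in relapse, 0.16 in ctrl, 0.65 in EDT and 0.28 in NT, so its p may be too small. The cytotoxic list passed as well without EDT replicate 2 (1.14), 5 (1.53), 6 (1.57) or 7 (1.49), the T cell list without EDT replicate 5 (1.45) or 6 (1.49), and the adipocyte list without NT replicate 7 (1.97).

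Over single genes, 1582 differed in their effect, 931 with the higher effect in EDT and 651 with the higher effect in relapse. Of 100 labellings of the tumours within each table, the real one included, 6 gave at least as many. Such shuffling does not keep an effect common to both comparisons, so it does not test equal effects. Nor is every labelling free of effects, since one near the real split of a table can keep part of that table's effect. The shuffled labellings that reached the count gave 1664 to 2224 genes, and no other gave more than 8. How close they lay to the real split was not examined, so the share cannot settle the question. The count is therefore not shown to stand out from chance. Syt4 had the highest difference, 6.58 ± 1.20, from 1.29 in EDT and -5.30 in relapse, and Ubd, with 4.85 ± 0.83, rose further in EDT. On the other side stood Ankrd1, an ankyrin repeat protein of stretched muscle (-4.14 ± 1.16), Gm9780 (-3.77 ± 0.56), Cfap58 (-3.77 ± 0.94), the protease gene Htra1 (-3.71 ± 0.89) and Phgdh, the first enzyme of serine synthesis (-3.61 ± 0.56). In relapse these rose by 4.25, 3.18, 2.96, 4.36 and 3.16. The effect on Met did not differ past the threshold (-0.50 ± 0.41, limma adjusted p = 0.419). The count was 1035 without relapse replicate 5, 2498 without relapse replicate 3 and 647 with median centring.

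The comparisons, which share no control arrays, had much in common. In both, 610 genes were called higher, against 184.1 for independent lists, and 634 lower, against 253.4, while 57 were called in opposite directions, against 434.9. Of these 57, 28 were higher in EDT and lower in relapse. Across genes, which are not independent replicates, the fold changes correlated with Pearson r = 0.62 and Spearman rho = 0.53, and 0 of 100 permuted labellings gave an r as high (range -0.53 to 0.61). The number called in opposite directions was 27 without relapse replicate 5, 31 without ctrl replicate 1 or relapse replicate 4, 34 without ctrl replicate 4, 35 without EDT replicate 4 and 97 without relapse replicate 3.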

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

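The tests of cell composition, of slide and of the neutrophil genes were chosen only after the results were seen, and the counts of other splits were planned.

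Of the 23 lists only the melanocyte list differed between the EDT effect and the relapse effect in limma (2.85), which pools the unequal spreads of the groups. Single melanocyte genes differed by 3.97 (Oca2), 3.91 (Trpm1), 4.16 (Pmel), 4.42 (Mlana), 4.14 (Rab38) and 4.04 (Tspan10). Outside that group Lncbate10 differed by 3.05 and Syt4 by 6.58. All but Syt4, which was 1.29 higher in EDT, were lower than in untreated tumours by more at relapse. Single genes with the higher effect in EDT were Ubd (4.85), Serpina3f (3.61), Acod1 (2.67), Nkg7 (2.46), Ctsw (2.96), Cd274 (1.77), Lag3 (2.32), Pparg (4.0), Fos (2.14), Atf3 (1.91) and Lpl (1.68). The fitted 2.34 for Cd3d is no exact amount, since neither control group detected it. The interferon list did not pass (0.48 ± 0.54, limma adjusted p = 0.663). Higher at relapse were the effects on the MHC class II invariant chain Cd74 (-2.37), Ly6e (-2.58), C1qc (-1.69), Ankrd1 (-4.14), Gm9780 (-3.77), Cfap58 (-3.77), Htra1 (-3.71) and Phgdh (-3.61). The tables lay on different slides and differed in treatment stage, and each effect was taken against the controls of its own table.

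Single tumours far from the rest of their group were marked where the gap to the nearest tumour exceeded Dixon's 95% critical value, which chance alone gives in about 1 of 20 groups. Over lists and array measures 3 of 100 groups held such a tumour, against 5 expected, and over named genes 32 of 296, against 14.8 expected. NT replicate 6 was low for the melanocyte list (11.39 on the log2 scale, against a median of 12.03 in the others), Trpm1 (8.86 against 12.18), Tspan10 (11.22), Rab38 (11.37), Lncbate10 (7.94) and the haemoglobin gene Hba-a1 (12.21), and high for Prkg2 (11.80). Relapse replicate 3 was high for Trpm1 (9.70 against 4.67), Lncbate10 (7.65), Cyp4b1 (8.61), Cyp4b1-ps2 (9.52) and Tbx4 (6.04), and low for Axl (12.07 against 14.00), Ly6e (11.63), C1qc (11.05) and Havcr2 (6.47). In these 9 genes it lay on the side of the untreated tumours, and its melanocyte score was the least reduced of the relapsed tumours.

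Control replicate 5 was high for Ubd (6.02), Serpina3f (6.78), Cxcl9 (10.61 against 6.35) and Cd79b (5.94), and low for the hypoxia list (10.01), for which EDT replicate 1 was high (10.79). Its Cd3g signal (4.89 against 4.38) was marked too, but no control tumour detected Cd3g. EDT replicate 5 was high for Cyp4b1 (8.55) and Cyp4b1-ps2 (9.01), and EDT replicate 2 low for Trpm1 (7.06). NT replicate 4 was high for Il1b (7.54) and low for Pparg (7.32), NT replicate 5 low for Top2a (8.38), NT replicate 8 low for Psmb8 (8.76) and NT replicate 7 high for Ankrd1 (8.30). Also far from their groups were control replicate 4 for Clec4e (5.80), control replicate 3 for Fn1 (7.27), relapse replicate 5 for Ccl7 (11.95) and relapse replicate 1 for Gab1 (10.61). No explanation was tested for these single tumours.

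Probes without a gene symbol took no part in the comparisons of genes. Of 2145 such probes past the detection filter, 517 differed between EDT and NT, 222 higher and 295 lower, which is 24.1%, and 651 between relapse and ctrl, 300 higher and 351 lower, which is 30.3%.

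Other splits of the tumours into groups of the same sizes, 100 in each comparison with the real split included, were fitted in the same way. In EDT against NT only 1, the real one, gave as many as 2831 genes, and the highest other gave 35. In relapse against ctrl again only 1 gave as many as 2944 genes, and the highest other gave 1911. For both counts 1 in 100 is the smallest share these splits allow, so they bound chance at that share and do not exclude it. For the difference of effects, with labels shuffled within each table, 6 of 100 gave at least the 1582 genes found, with 2224 in the highest other. Such shuffling does not keep an effect common to both comparisons, so it does not test equal effects. A labelling near the real split of a table can also keep part of that table's effect, so not every labelling is free of effects. Chance is not excluded for that count either.

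The melanocyte list was lower while leukocyte lists were higher, so a changed mix of cells may account for part of it. Loss of tumour cells alone would raise all other cell types alike, but the endothelial list lay below the macrophage list, with a difference of changes of -2.21 ± 0.18 in EDT (SE, exact permutation p = 0.000155, the smallest the splits allow) and -2.16 ± 0.30 in relapse (exact permutation p = 0.00794, also the smallest), which argues against it as the whole cause. Dilution by incoming leukocytes would lower melanocyte and endothelial genes alike. Their changes differed by -3.69 ± 0.97 in relapse (exact permutation p = 0.00794), which argues against dilution alone there, and by -0.45 ± 0.32 in EDT (exact permutation p = 0.193), which leaves it open. Replacement of tumour cells by leukocytes with a constant share of vessels, and a lower expression per tumour cell at either stage, stay open in both. The changes of these lists were known when the tests were chosen, so the p-values add no separate evidence to them.

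NT and EDT tumours lay mostly on different slides, so a difference between slides may add to any list difference. On slide 5, which held both groups, 11 of 11 immune lists were higher in EDT by more than 2 SE, which argues against slide as their whole cause. With slide as a fixed block, however, the neutrophil (1.77, limma adjusted p = 0.145), acute inflammation (1.64, limma adjusted p = 0.081) and B cell lists (0.80, limma adjusted p = 0.103) lost their calls. Over all slides these differences were 2.07, 1.84 and 0.54, so their size was largely kept. Within slide 5 alone the first (limma adjusted p = 0.0267) and second (limma adjusted p = 0.0222) passed, and the B cell list did not (limma adjusted p = 0.15). The fits differ, so for these 3 slide stays open. The endothelial list was lower on slide 5 as well (-0.70 ± 0.35), only just beyond 2 SE. For the neural crest list (0.38 ± 0.40) and the melanocyte list in EDT (-0.53 ± 0.40) slide and treatment cannot be told apart, because 2 against 3 tumours leave both open. NT replicate 6, low for the melanocyte list, is 1 of these 3, and without it the difference was -0.72 ± 0.63.

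Neutrophil genes rose in EDT, and other cells may carry some of them. The 4 members that epidermis also expresses, S100a8, S100a9, Lcn2 and Stfa1, changed by 0.78 ± 1.04 more than the keratinocyte list (exact permutation p = 0.476). The 9 other members were higher by 2.04 ± 0.40 (exact permutation p = 0.000311), by 0.68 ± 1.57 more than the keratinocyte list (exact permutation p = 0.662). Activated keratinocytes can make some of the 9, such as Camp, Mmp9 and Il1r2, so keratinocytes stay open as a source of both sets. The difference between the 9 members and the macrophage list, 0.38 ± 0.27 (exact permutation p = 0.173), does not separate neutrophils from macrophages and monocytes, which express part of the 9.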

How the results depend on the processing

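Leaving out the 3 arrays of slide 1, centring scores within slide and leaving out 1 control tumour on slide 5 and on slide 7 were chosen only after the data were seen, and all other alternatives were planned. With an alternative in 1 choice, leaving out single tumours aside, 132 main results (counts of genes and lists, overlaps and relations) kept their direction and their side of the threshold or a count within 1.5 times, and 19 did not. Of single genes and lists, 1992 kept direction and side, 122 no longer passed, 27 newly passed and 35 turned direction. For camera and fry the direction of a list was read from its score difference, a choice made after the values were seen. The call of HGF and MET in relapse by fry, counted as newly passed, was lower where the score was higher. Except where the construction is named, the cause was not tested.

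The 19 main results follow. Median centring left 647 genes in the difference of effects and 22 genes called in opposite directions, and gave r = -0.67 for neutrophils with melanocytes in EDT (adjusted exact p = 0.132). Without a detection filter 30 genes were called in opposite directions. With slide as a fixed block EDT and NT differed in 1045 genes, 891 of them shared with the 2831, and in 8 lists, and within slide 5 in 480 genes, 454 shared, where fewer tumours enter. Within slide 6 relapse and ctrl differed in 568 genes, 544 shared, and within slide 7 in 5 lists, 4 shared. The 2-fold minimum, which by construction can only remove genes, left 854 and 1832. Camera with an estimated correlation called 0 lists in EDT and 0 in relapse, while fry called 14 and 13 and camera with a preset correlation 14 and 11. Spearman's rho put T cells with melanocytes in NT past the threshold (0.857). With scores centred within slide the 3 relations in EDT kept r (-0.94, -0.87 and 0.81) and no longer passed (adjusted exact p = 0.0833), where only 72 orders enter. In NT T cells with neutrophils (-0.41) and neutrophils with melanocytes (-0.52) turned.

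Scaling decided how the calls were shared between directions. Median centring moved the median change of all genes from -0.05 to 0.29 in EDT and from -0.07 to 0.30 in relapse, and 92.9% and 76.1% of the genes called were then higher, against 48.9% and 43.1%. The authors' values gave 69.8% and 53.9%. No control transcript of known amount was used here to decide between the scalings. A global shift of that size leaves the larger list differences in place: the melanocyte list was still lower, while the endothelial call in EDT (-0.18, adjusted exact p = 0.351) and the adipocyte call in relapse (-0.85, adjusted exact p = 0.158) ended. Without slide 1, 2305 genes differed, 2005 shared, and 14 lists passed, 13 shared. The endothelial list was lost and the immediate early list gained (0.76, adjusted exact p = 0.018).

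Replicate numbers were not taken to pair the tumours, since not every pair correlated over 0.1. After the mean change was removed, equal numbers correlated with r between -0.05 and 0.18 in the first table, over 0.1 in 1 of 8 with 1 of 8 best with its own number, and between -0.06 and 0.34 in the second, over 0.1 in 3 of 5 with 3 of 5 best with their own number. With the replicate number as a block 2514 and 3113 genes and 14 and 13 lists passed. In relapse the neural crest (limma adjusted p = 0.0163) and neutrophil lists (limma adjusted p = 0.038) were gained.

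Lists and genes that turned direction had values near 0 or wide errors. Without background correction these were hypoxia in EDT (-0.0158), immediate early genes in relapse (-0.0120) and the difference of effects for acute inflammation (0.0373). With the authors' values HGF and MET (0.0481) and muscle (0.11) turned in EDT, and endothelial (0.0165) and muscle (0.0861) in relapse. Median centring turned Hba-a1 (0.22), HGF and MET (0.25) and muscle (0.30) in EDT, and endothelial (0.27) and muscle (0.26) in relapse. With no filter HGF and MET in EDT (0.0218), immediate early in relapse (-0.0512) and the muscle difference of effects (-0.0263) turned, with a detection p of 0.05 immediate early in relapse (-0.0448), and with the mean over probes hypoxia in EDT (-0.0383) and immediate early in relapse (-0.0047). A random slide block turned muscle in EDT (0.20). As a fixed block and within slide 5 alike, slide turned Krt14 (-0.46), Hba-a1 (0.0904), hypoxia (-0.26), keratinocyte (-0.42), muscle (1.21) and erythroid genes (0.24) in EDT. Slide 6 turned muscle (0.91) and immediate early (-0.13) and slide 7 Myl1 (-0.80) and endothelial (0.46) in relapse.

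With each tumour left out in turn, 205 main values stayed and 25 did not. EDT against NT gave between 2340 and 3099 genes and 14 and 15 lists, relapse against ctrl between 2126 and 3938 genes and 9 and 12 lists, and the difference of effects between 1035 and 2498 genes and 1 and 3 lists. Genes called the same way numbered 1012 to 1444 and in opposite directions 27 to 97, and the correlation of fold changes ran from 0.589 to 0.646. In EDT r ran from -0.980 to -0.878 for T cells with melanocytes, 0.698 to 0.883 for T cells with neutrophils and -0.956 to -0.841 for neutrophils with melanocytes. In NT it ran from 0.575 to 0.813, -0.044 to 0.513 and 0.147 to 0.408. Direction turned without some tumour for Hba-a1 (-0.37 to 0.10), hypoxia (-0.0559 to 0.153) and muscle (-0.46 to 0.37) in EDT, for Myl1 (-0.32 to 1.12), endothelial (-0.328 to 0.0791), immediate early (-0.0982 to 0.0575) and muscle (-0.65 to 0.82) in relapse, and in the difference of effects for erythroid (-0.15 to 1.30), fibroblast (-0.64 to 0.30), neutrophil (-0.16 to 0.69), acute inflammation (-0.25 to 0.25) and muscle (-0.84 to 0.63). Of other single genes and lists 2581 stayed, 39 no longer passed, 15 newly passed and 49 turned.

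Cd8a, Cd4, Gzmb and Hgf did not pass the detection filter. Whether their transcripts were low or their probes gave little signal was not tested.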

Other observations

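The gene families here and all tests on them were chosen only after the values were seen, and of the tests of Phgdh and Ankrd1 the bounds were written before and the verdict was changed after.

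Interferon-inducible guanylate-binding proteins, which attack vacuoles that hold pathogens, rose in 5 of 5 members in EDT, with a mean change of 3.54 ± 0.27 (SE, n = 8 and 8), and in 4 of 5 in relapse (2.16 ± 0.67). Gbp3 rose by 4.36 in EDT and 2.99 in relapse. Chemokine ligands, which draw leukocytes, rose in 19 of 24 in EDT, where 1 fell, and in 13 of 24 in relapse, with mean changes of 2.11 ± 0.31 and 1.95 ± 0.16. For the CC ligands alone these were 1.73 and 1.65 and for the CXC ligands 2.36 and 2.06. C-type lectins, receptors by which myeloid cells sense sugars, rose in 11 of 14 in EDT (1.66 ± 0.24) and in 6 of 14 in relapse (1.32 ± 0.20). Among these the dendritic cell receptors Clec4a1, Clec4a3 and Clec4b1 rose by 2.25, 1.68 and 1.53 in EDT and by 3.67, 3.68 and 3.60 in relapse, while the beta-glucan receptor Clec7a rose by 3.40 in EDT and had a change of 1.07 in relapse that did not pass. Complement genes rose in 5 of 8 in EDT (1.41 ± 0.19), including factor B (Cfb, 3.31), and in relapse 4 rose and 2 fell (0.49 ± 0.27, adjusted exact p = 0.122), with C1qb at 3.20 and C4b at -2.77.

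Cholesterol synthesis genes fell in 9 of 16 in EDT, with Tm7sf2 at -1.95, Nsdhl at -1.17 and Mvd at -1.15, and a mean change of -0.71 ± 0.20 (adjusted exact p = 0.00953). Camera with an estimated correlation gave an adjusted p = 0.291, and the mean change on slide 5 was -0.35. With median centring, which moved the median of all genes to 0.29, the mean was -0.37 and 1 member fell, but relative to that median it was -0.67, against -0.66 in the first scaling. In relapse it was -0.23 ± 0.27 (adjusted exact p = 0.444) and turned to 0.13 with median centring. Subunits of respiratory complex I fell in 18 of 34 in EDT and 2 rose, with a mean of -0.28 ± 0.05, which turned to 0.05 with median centring (relative to all genes -0.23 and -0.24), and in relapse 5 fell (-0.39 ± 0.12, adjusted exact p = 0.0484). For complex I camera with an estimated correlation gave an adjusted p = 0.181 in EDT and 0.48 in relapse. Subunits of the vacuolar proton pump, which acidifies lysosomes and melanosomes, fell in 6 of 13 in EDT, where 1 rose, and in 7 of 13 in relapse, with means of -0.33 ± 0.09 and -0.66 ± 0.12, among them Atp6v0a1 (-1.65) in relapse. With median centring these were 0.01 and -0.40. Proteasome subunits, some of them in the MHC class I list, rose in 10 of 34 and 11 of 34, with means of 0.33 ± 0.05 and 0.59 ± 0.11.

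In all 16 families were looked at, and 22 of the 32 tests passed after adjustment over them. The CC and CXC ligands are part of the chemokine ligands, and several families share genes with the fixed lists, such as Gbp3 and C1qb. These tests are therefore not independent of each other and in part repeat the lists. With an estimated correlation 0 passed in EDT and 3 in relapse, the chemokine ligands together (adjusted p = 0.00956), the CC (adjusted p = 0.0136) and the CXC ligands (adjusted p = 0.0456). Of 13 families called in EDT, 13 had the same direction on slide 5, and 10 kept the call with slide as a fixed block. Lost were cholesterol synthesis (-0.35 on slide 5, limma adjusted p = 0.21), the vacuolar proton pump (-0.22, limma adjusted p = 0.223) and cytosolic ribosomal proteins (0.0619, limma adjusted p = 0.638). The effect differed between EDT and relapse in 0 of 16 families (limma). Schlafens (2.03 and 1.91 in EDT and relapse) passed in both. Cathepsins with lysosomal membrane proteins (0.62 and 0.20) and cytosolic ribosomal proteins (0.16 and -0.01, the latter 0.15 with median centring) passed in EDT and not in relapse. Collagens (0.46 and 0.71), histones (0.05 and 0.27) and mitochondrial ribosomal proteins (-0.04 and -0.02, and 0.32 and 0.30 with median centring) passed in neither.

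Phgdh rose in relapse by 3.16, and a stress response to lack of amino acids, run by the factor ATF4, may be a cause. The score of 13 other ATF4 targets was higher by 0.57 ± 0.34 in relapse (exact permutation p = 0.135), with 2 of 13 past the threshold, Asns (2.09) and Psat1 (0.72). In EDT, where Phgdh had a change of -0.45, the same list was higher by 0.31 ± 0.11 (exact permutation p = 0.0131), with 5 members higher and 2 lower. Ankrd1 rose in relapse by 4.25 and is a target of the YAP and TEAD factors. The score of 11 other targets differed by 0.18 ± 0.28 in relapse (exact permutation p = 0.548), with 3 higher and 2 lower, and by 0.06 ± 0.06 in EDT (exact permutation p = 0.356). Both lists met the bound written beforehand as counting against the explanation, a difference under 2 SE. That bound was wrong for 5 against 5 tumours, since differences up to 1.25 and 0.74 lie within 2 SE and the YAP members went both ways, so both explanations stay open.

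Of the neutrophil list, the 9 members other than S100a8, S100a9, Lcn2 and Stfa1 were higher in relapse as well (1.22 ± 0.31, exact permutation p = 0.00794), and those 4 had differences of 2.13 ± 1.17 in EDT (exact permutation p = 0.0914) and 2.76 ± 1.39 in relapse (exact permutation p = 0.0794). In relapse neither set was tested against the keratinocyte or the macrophage list, so other cells stay open as a source there too.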
